A study of Mus musculus with 5 samples.

How the data were processed

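H3K9me3, a histone mark of silent chromatin, was profiled by CUT&Tag in CD8+ T cells from the spleen of mice that carry the OT-I T cell receptor and Cas9. In CUT&Tag an antibody directs a protein A-Tn5 transposase to the chromatin that carries the mark, and the transposase cuts and tags the DNA there. The cells were electroporated with Cas9 ribonucleoprotein holding a guide against Prdm12 (sgPrdm12) or a non-targeting guide (sgNTC), at 300 pmol of guide and 300 pmol of Cas9, and recovered for 72 hours, per the labels. There were 2 libraries per group. The labels put replicate 1 of both groups in batch 1 and replicate 2 in batch 2, so the replicate number pairs the libraries by batch. Across regions, the difference between replicates 1 and 2 in sgNTC and that in sgPrdm12 had a correlation of 0.0035. With median counts of 7 and 9 per region in sgNTC, counting error can hide a shift shared by a batch, so none is excluded. Libraries correlated at 0.42 within sgNTC and 0.55 within sgPrdm12. Between groups the values were 0.49 in batch 1, 0.41 in batch 2, 0.39 for sgNTC-1 with sgPrdm12-2 and 0.52 for sgNTC-2 with sgPrdm12-1. The sgNTC libraries were thus less alike than some pairs from opposite groups. The IgG library was not analysed here. Whether the libraries came from separate animals is not given in the sources used here, so p-values measure only the spread between these libraries, which may be technical.

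The authors deposited 1 table of 46409 regions with a read count and a normalized signal per region and library. The deposited counts are whole numbers that were not normalized. The deposited normalized signal is the count times 1 constant per library, namely 1.29 and 1.09 for sgNTC-1 and sgNTC-2 and 0.638 and 1.12 for sgPrdm12-1 and sgPrdm12-2. How the authors derived the constants is not given in the sources used here. The submitters' processing notes name Trimmomatic, Bowtie2, MACS2 and DiffBind without versions, and how regions were called and merged is not given in the sources used here. A region set called with more weight on the deeper sgPrdm12 libraries would favour regions high in that group. The notes name the build GRCm39. However, by chromosome lengths that were recalled and not read from a supplied file, 66 regions on 8 chromosomes lay past the ends of GRCm39 and 0 past those of GRCm38, and 2 regions overlapped the ribosomal pseudogene Rn18s-rs5 at its position in the supplied GRCm38 gene table, so coordinates were read as GRCm38. They are printed as the table lists them, and whether its starts count from 0 or 1 is unknown.

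The design had assumed that the table would name genes. It has no such column, so regions were joined to the gene spans of the RefSeq table for GRCm38. A region took the name of the gene it overlapped, protein-coding genes first, or else of the nearest gene within 5 kb. Counts per gene were summed over all regions within 5 kb of the span of a protein-coding or lncRNA gene, so neighbouring genes can share a region. Region classes were gene end (within 3 kb of either end of a protein-coding span, since the gene table used here gives no strand), gene body, other gene and intergenic.

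Regions and genes were tested with edgeR's quasi-likelihood test (edgeR 4.0.16, limma 3.58.1, R 4.3.3) on the counts, with TMM factors, filterByExpr, no block, two-sided, and Benjamini-Hochberg adjusted p under 0.05. The standard error of a region or gene is the size of the log2 fold change divided by the square root of the quasi-F value. For medians over sets of regions the SE comes from a bootstrap over regions, so it holds no spread between libraries. Values per group are CPM, that is, counts per 1e6 of library size, on the TMM scale. Gene lists, region classes and chromosomes were tested with camera at a preset correlation of 0.01, for lists with at least 5 measured genes. All 21 gene lists were fixed before the data were examined, as was the rule that picks the named items by their values in these data. The rule takes the 12 called regions with the largest and the 12 with the smallest log2 fold change, with 1 region per gene. Eligible regions had a mean of at least 20 counts, an assigned gene and both sgPrdm12 libraries on the same side of both sgNTC libraries. The 2 members of each tested list with the smallest p, and Prdm12, were named as well. Of the named lower regions, 1 is not reported here by name. Genes named outside this rule are said to be so.

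Alternatives were DESeq2 size factors, total counts, no filter, a replicate block, each library left out, DESeq2 1.42.0 and limma-voom, an adjusted p threshold of 0.1, an estimated correlation and the region as the unit. The authors' constants, with and without a replicate block, leaving out the 10 most covered regions, gene spans without flanks and gene ends of 1000 bp were added after seeing the data. On simulated counts for 30923 regions with the real means and library sizes, the region test recovered 3.64% of regions changed by 1 on the log2 scale, 31.7% of those changed by 2 and 96.9% of those changed by 4, with 2 false calls among 85.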

Results

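H3K9me3 was measured over 46409 regions in 2 sgNTC and 2 sgPrdm12 libraries of mouse CD8+ T cells. Of the regions, 61.8% were intergenic, 23.1% lay in the body of a protein-coding gene, 9.03% in another gene and 6.15% at a gene end. Their median width was 282 bp and they covered 15.2 Mb. Library totals over the regions were 843673 and 1060646 for sgNTC-1 and sgNTC-2, and 2353807 and 1396201 for sgPrdm12-1 and sgPrdm12-2. Median counts per region were 7 and 9 against 32 and 17, so most single regions in sgNTC rested on few reads.

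The 10 most covered regions took a larger share of the reads in sgNTC. They held 39.8% (Wilson 95% interval 39.7 to 39.9) of the counts in sgNTC-1 and 44.0% (43.9 to 44.1) in sgNTC-2, against 18.4% (18.4 to 18.5) in sgPrdm12-1 and 22.4% (22.3 to 22.4) in sgPrdm12-2. The intervals cover counting error only. The most covered region, at chromosome 2 positions 98666550 to 98667323 and outside any gene, alone held 19.4%, 22.1%, 8.43% and 10.4%. On the authors' normalized scale, the median region stood at 9.01 and 9.80 in sgNTC and at 20.4 and 19 in sgPrdm12. The choice of scale therefore sets the direction of the typical region. The median log2 fold change, sgPrdm12 over sgNTC, was -0.01 with TMM, 0.56 with total counts and 1.00 with the authors' constants. Changes below are on the TMM scale, that is, relative to the median region.

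**Figure D1:**
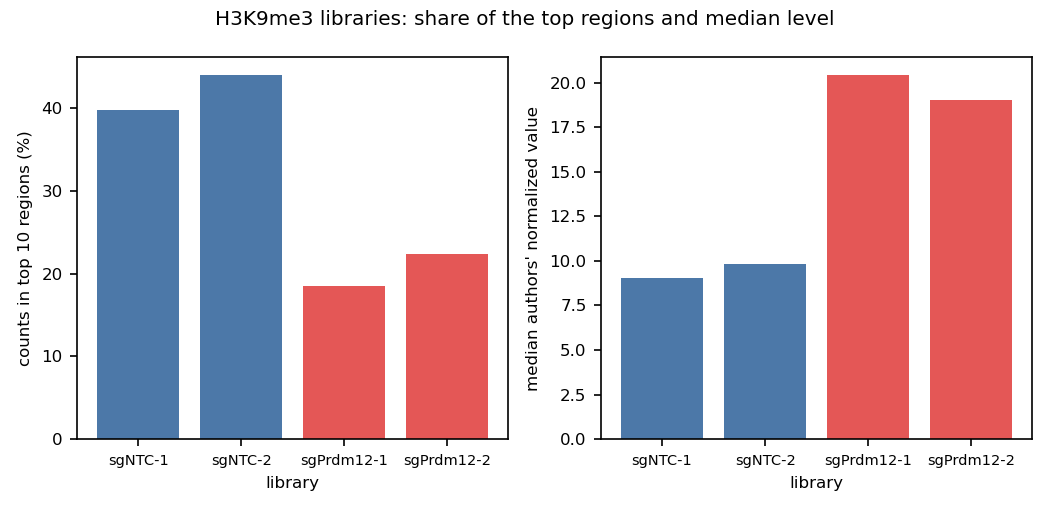
Bars show, for each of the 4 libraries, the percentage of counts in the 10 most covered regions (left) and the median of the authors' normalized value over all regions (right, in the authors' normalized counts). The sgNTC libraries have the higher share, 39.8% and 44.0%, and the lower median, 9.01 and 9.80.

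Prdm12, the gene targeted by the guide and known as a regulator of pain-sensing neurons, had 4 regions within 5 kb of its span on chromosome 2. Their summed count was 64 and 51 in the sgNTC libraries and 303 and 197 in the sgPrdm12 libraries, or 74.6 ± 18.8 and 111 ± 13.9 CPM (SD, n = 2). The log2 fold change was 0.58 (SE 0.24) and did not pass the edgeR test (adjusted p = 0.227). It was 0.20 in batch 1 and 0.97 in batch 2. On the authors' scale the value was 1.59 and passed (edgeR, adjusted p = 4.61e-10). H3K9me3 at the locus does not measure editing of the gene.

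The comparison of regions addressed which sites differ in H3K9me3 after targeting of Prdm12. Relative to the median region, 41 regions were higher and 141 lower in sgPrdm12. A gene lay within 5 kb of 31 of the higher regions, among them Flg2 and Stat5b, and of 82 of the lower ones. Of the lower regions 27 lay in the first 0.2 Mb of assembled sequence of a chromosome, where 0 were higher. At the start of chromosome 9, 16 of 17 tested regions were lower. Lower regions also lay at Rn18s-rs5 and AY036118, named after their values were seen, which neighbour each other in the ribosomal RNA-related stretch of chromosome 17. Reads from repeated sequence of this kind can be split between copies, so these values are uncertain.

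Among the higher regions, the one in Flg2, a filaggrin family gene of the skin barrier, on chromosome 3 at 93211667 to 93212031, held 5 and 3 counts in sgNTC and 118 and 77 in sgPrdm12. Its log2 fold change was 3.05 (SE 0.52, edgeR adjusted p = 7.06e-05). The region in Stat5b, a transcription factor of interleukin-2 signalling, on chromosome 11 at 100804384 to 100804797, rose by 2.84 (SE 0.57, edgeR adjusted p = 0.00175), with 4 and 3 counts against 100 and 52. Without sgNTC-2 or with limma-voom neither Flg2 nor Stat5b passed, and Stat5b did not pass without sgNTC-1 either. Regions in Hp1bp3, which encodes a heterochromatin protein 1 binding protein, Plec, which encodes the cytoskeletal linker plectin, and Zfp68, a zinc finger gene, rose by 2.99, 2.93 and 2.74. Regions in 1700128A07Rik, Stk19 and Dlgap2, the last a gene of the postsynaptic density, rose by 3.71, 2.98 and 2.20. Regions beside Wdr12, a ribosome biogenesis gene, Rpl17-ps10, Gm36126 and Vipr1, a receptor for vasoactive intestinal peptide, rose by 2.78, 2.65, 2.56 and 2.5. In each of these 12 regions the sgNTC libraries held 8 counts or fewer. Hp1bp3 and 1700128A07Rik did not pass whichever library was left out. With DESeq2 size factors only Flg2 and Stat5b passed, and with limma-voom 0 of the 12 did.

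Among the lower regions, those at the RNA genes Rpph1 and Rmrp, the RNA parts of the nucleases RNase P and RNase MRP, fell by 3.45 (SE 0.46) and fell by 3.36 (SE 0.42). Rpph1 held 341 and 83 counts in sgNTC and 142 and 0 in sgPrdm12, and Rmrp 147 and 41 against 58 and 4, so the replicates differed widely at both. Neither passed without sgNTC-1, with DESeq2's Wald test or with limma-voom. The region in Jarid2, which encodes a partner of Polycomb repressive complex 2, on chromosome 13 at 44869571 to 44870007, had 161 and 54 counts against 80 and 61 and fell by 2.16 (SE 0.35, edgeR adjusted p = 1.55e-05). The value for Jarid2 was -3.04 in batch 1 and -0.79 in batch 2, and it did not pass without sgNTC-1, with DESeq2's Wald test or with limma-voom. The region at the end of Cdk4, a cell cycle kinase, fell by 2.16. Regions in Icmt, Nfya, a subunit of the transcription factor NF-Y, and Camk1d fell by 2.57, 2.55 and 2.15. Cdk4, Icmt, Nfya and Camk1d did not pass without sgNTC-1, and Icmt did not pass with limma-voom either. Regions in Gm30101 and Gm30821 and beside Gm21758 and Rps2-ps5 fell by 2.36, 2.16, 2.24 and 2.23. Among these, only Gm30101 passed without sgNTC-1. For Gm21758 and Rps2-ps5 sgPrdm12-2 stood far below sgPrdm12-1, with 0 against 68 and 34 against 671 counts.

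The edgeR test covered 37390 regions, of which 2398 had an unadjusted p under 0.05. The split depended on the scale, with 7765 higher and 52 lower with the authors' constants, 936 and 79 with total counts, and 3 and 57 with DESeq2 size factors. Under all 4 scales, 3 regions were higher and 44 lower, among them Flg2 and Stat5b, and Rmrp, Icmt, Nfya, Gm30101, Jarid2, Cdk4, Gm30821 and Camk1d. Of these, Flg2 and Stat5b did not pass without sgNTC-2. Without sgNTC-1, Stat5b, Rmrp, Icmt, Nfya, Jarid2, Cdk4, Gm30821 and Camk1d did not pass. The 44 lower regions also include the most covered region of all and heavily covered regions at the start of chromosome 9. The 4 scales use the same counts and differ only in 1 factor per library, so passing all of them is not separate evidence. Each library mattered to the counts of higher and lower regions, which were 9 and 29 without sgNTC-1, 7 and 38 without sgNTC-2, 56 and 219 without sgPrdm12-1 and 6 and 175 without sgPrdm12-2. Of the 12 and 12 named regions, 3 and 2, 1 and 11, 7 and 12, and 3 and 11 passed in these fits. With DESeq2 and limma-voom, 6 and 1 regions were higher and 131 and 111 lower.

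**Figure D2:**
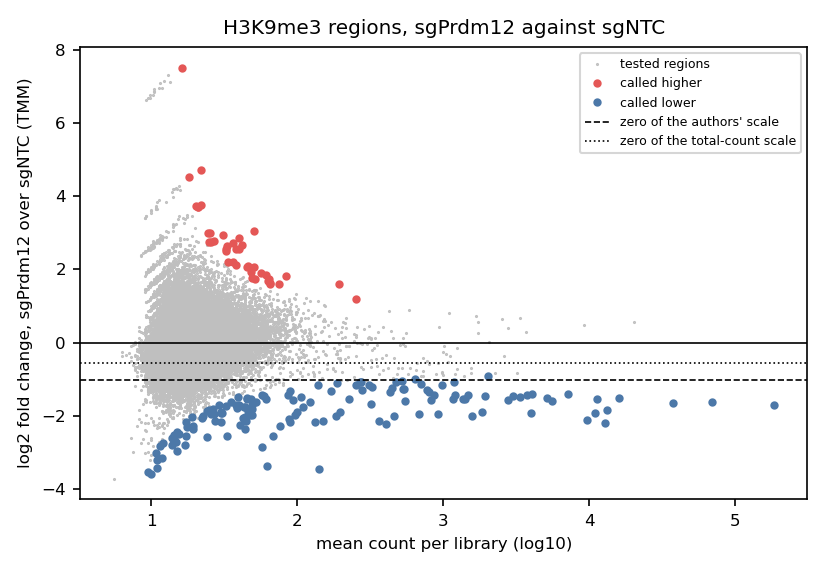
Each point is a tested region, with its mean count per library on a log10 axis and its log2 fold change, sgPrdm12 over sgNTC, on the TMM scale. The 41 regions called higher have a median mean count of 38.3, the 141 called lower have one of 89 and include the most covered region, and the broken lines mark where 0 lies with total counts and with the authors' constants.

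**Figure D3:**
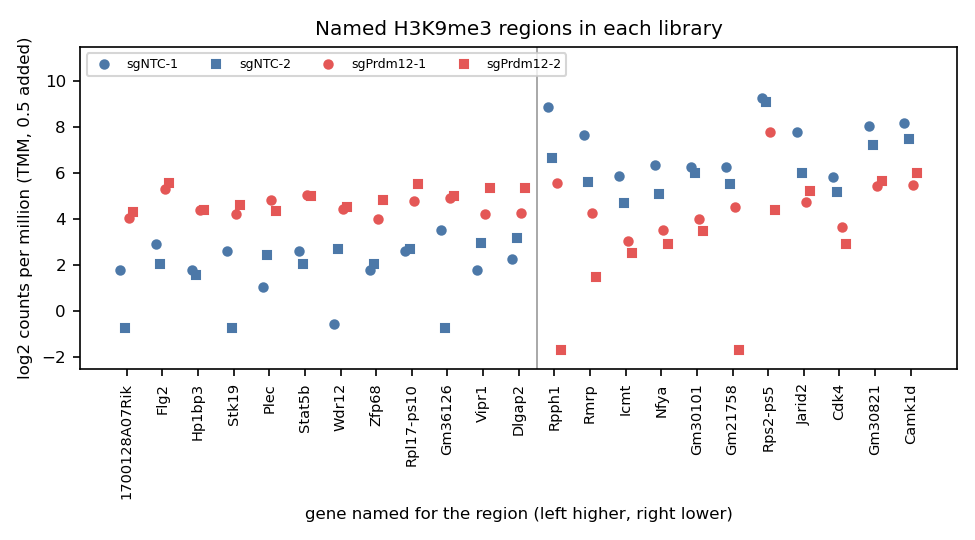
Points give log2 CPM on the TMM scale, after adding 0.5 counts, of named regions in each library. In all of those shown both sgPrdm12 libraries lie on the same side of both sgNTC libraries, and sgPrdm12-2 is far below sgPrdm12-1 at Rpph1, Gm21758 and Rps2-ps5.

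Summed over the regions of a gene, 89 genes were higher and 137 lower in sgPrdm12 among 7774 tested (edgeR, 927 with an unadjusted p under 0.05). Because neighbours can share regions, these calls rest on 81 and 110 distinct sets of regions, and 55.7% of the tested genes had 1 region. For a gene of 1 region both fits use the same counts, yet the gene fit could give a much smaller p. For Gm525 the edgeR adjusted p was 0.308 as a region and 2.64e-05 as a gene. A gene call whose regions did not pass is therefore not added evidence by itself. The following genes were chosen after their values were seen. Flg2 and its neighbour Flg, both genes of the skin barrier, rose by 1.61 (SE 0.17) and 1.23 (SE 0.22), over 12 and 6 regions. Plec rose by 2.12 and Ahnak2 by 1.76. Among genes known in lymphocytes, Fyn, a kinase of T cell receptor signalling, rose by 0.99 with edgeR adjusted p = 0.00502, Stat5b by 1.15, Gimap4 by 1.18, Slfn2 by 1.94, Pag1 by 1.67 and Il10rb, a chain of the interleukin-10 receptor, by 1.34. Slfn2 rests on 1 region, with 0 and 16 counts in the sgNTC libraries, and Gm20234 has the same counts from 1 region. The genes known in lymphocytes were picked from those that rose and were not tested as a group. In the fixed lists of T cell biology, 0 genes rose or fell over all genes tested. Genes that fell included the heat shock gene Hspa8, which fell by 1.40, and Dnajb9, which fell by 1.76. Wee1 and Fzr1 of the cell cycle fell by 1.85 and 1.93, and Tob1 fell by 1.43. Each of these falls rests on 1 region, and whether that region passed by itself is not given here. On the authors' scale the falls of Hspa8, Dnajb9, Wee1, Fzr1 and Tob1 did not pass, with edgeR adjusted p from 0.0723 for Fzr1 to 0.444 for Tob1. The neural adhesion gene Chl1 fell by 1.60, with 4792 and 6610 counts against 6798 and 4123. Nearly all of these lay in 1 region of chromosome 6, at 103649048 to 103649286, with 4788 and 6606 against 6777 and 4119. The value is therefore that of this region and not of the gene as a whole. Repeats were not annotated, so whether the region is repeated sequence is unknown.

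The counts of genes higher and lower moved to 3445 and 32 with the authors' constants, 1177 and 70 with total counts, and 29 and 101 with DESeq2 size factors. They were 15 and 72 without sgNTC-1, 15 and 70 without sgNTC-2, 63 and 184 without sgPrdm12-1 and 22 and 147 without sgPrdm12-2.

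Zinc finger genes, a family whose clusters are known to carry H3K9me3, were higher as a group by the camera test at its preset correlation. The group did not pass without sgNTC-1 or with an estimated correlation (camera in limma, p = 0.0284, adjusted p = 0.369). The estimate for these genes was -0.00036, below the preset correlation, so correlation between them does not account for the larger p. With an estimated correlation camera also takes its p from the degrees of freedom left by the 4 libraries, which are few. How much this raised the p was not examined. Of 134 measured members, 4 rose and 0 fell over all genes tested, and 8 rose and 1 fell adjusted over the list alone, while 27 had an unadjusted p under 0.05. Their median log2 fold change was 0.25, which is 0.29 above that of all genes, and 69.4% lay above the median of all genes. Zfp110 rose by 1.51 (SE 0.33, edgeR adjusted p = 0.000641), and Zfp867 by 1.41. The value for Zfp867 rests on 1 region that is also the only region of its neighbour Jmjd4, so it cannot be assigned to either gene. The other genes of the list that rose, named after their values were seen, were Zfp850 by 1.17 and Zfp469 by 1.00. The camera test gave adjusted p = 0.0017 in limma. Without sgNTC-1 the mean shift was 0.15, and Zfp110 and Zfp867 did not pass when either sgNTC library was left out.

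No other list passed the camera test on the TMM scale. Of 271 olfactory receptor genes, 1 rose, Olfr585 by 1.29, and the median was -0.21. This list passed with total counts (limma, adjusted p = 0.012) and the authors' constants (limma, adjusted p = 0.000431). Its mean shift relative to all genes was -0.14 with TMM and with both of these scales, so only the p changed. Olfr585 did not pass with DESeq2 size factors or without any of the 4 libraries. Olfr357 stood at -1.64 (edgeR, adjusted p = 0.0638), with -0.52 in batch 1 and -3.99 in batch 2, and without sgPrdm12-1 it passed at -3.74 relative to the median gene. Of 53 clustered protocadherin genes 0 changed. Their mean was 0.07 above that of all genes and their median -0.04. The list passed with total counts and the authors' constants (limma, adjusted p = 0.0456 and 0.000475), where the mean shift was again 0.07. On the TMM scale the estimated correlation between the protocadherin genes was 0.54, and with the region as the unit the shift was -0.016. Estimated correlations were not tried with total counts or the authors' constants, for this list or the olfactory one. Pcdhb7 stood at 0.98 and Pcdhb6 at 0.65. Both were short of the threshold on the TMM scale and passed with total counts and the authors' constants.

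Lists of T cell biology held few measured genes. Of 7 measured effector genes 0 changed over all genes tested and 1 fell adjusted over the list alone. This was Zeb2, a transcription factor of effector T cells, at -1.59 (SE 0.50, edgeR adjusted p = 0.0504). Without sgPrdm12-1 Zeb2 passed (edgeR, adjusted p = 0.0424), and on the authors' scale it stood at -0.57 with edgeR adjusted p = 0.365. The list's median was 0.11 and its mean shift -0.08, so they differ in sign, and Il2ra stood at 0.55. Of 5 naive, memory and stem-like genes 0 changed over all genes tested and 1 rose adjusted over the list alone. It was Il6ra, at 1.02 with edgeR adjusted p = 0.143, and Il7r, the interleukin-7 receptor, stood at 0.86. The 7 measured MHC genes had a median of 0.42 and 0 changed, with H2-D1 at 1.27 and H2-Aa at -0.54. These counts of changed genes hold on the TMM scale only, since Il6ra, Il7r and H2-D1 passed with total counts (edgeR, adjusted p = 0.000796, 0.0129 and 0.00501) and with the authors' constants, and Il2ra passed with the latter. For the lists with under 5 measured genes no set test was run, and 0 genes changed. These were the inhibitory receptor and exhaustion list with 3 measured genes, T cell receptor and identity with 3, survival and apoptosis with 2, killer-cell lectin-like receptors with 3, and the markers of other cells, with 0 for B cells, 2 for myeloid cells, 4 for NK and innate cells and 2 for erythroid cells.

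Lists of chromatin and developmental genes did not change as groups on the TMM scale either. Of 6 measured genes of the H3K9 methylation machinery 0 changed, with Cbx3, which encodes a heterochromatin protein 1 family member, at 0.75 and Setdb2 at 0.99. On the authors' scale both passed (edgeR, adjusted p = 7.71e-06 and 0.0368), and Cbx3 did so with total counts too. Of 5 PRDM family genes 0 changed, with Prdm12 as above and Prdm16 at -0.57. Of 7 nociceptor and neural crest genes 0 changed, with Isl1 at -0.63 and Tac1 at 0.58. The same held for 90 vomeronasal and taste receptors, with Vmn1r238 at -0.70 and Vmn2r77 at -1.01 (-1.93 and past the threshold without sgPrdm12-1), for 35 cytochrome P450 genes, with Cyp20a1 at 0.77 and Cyp2d12 at 1.42, for 6 germline genes, with Tdrd9 at 0.48 and Asz1 at -0.49, and for 16 imprinted genes, with Rasgrf1 at -0.67 and Peg10 at 2.81. Peg10 rested on 0 and 2 counts in sgNTC. On the authors' scale Tac1, Cyp20a1, Cyp2d12, Tdrd9 and Peg10 passed, and Cyp20a1 and Tdrd9 did so with total counts. By limma's camera test, the adjusted p of each of the 12 lists that did not pass was 0.774, and 0 lists passed with an estimated correlation.

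Regions at gene ends stood lower than the mean of all regions, by -0.13 over 2407 tested regions, of which 6 were higher and 29 lower. The class did not pass (camera in limma, adjusted p = 0.0933, and adjusted p = 0.063 with an estimated correlation). With gene ends of 1000 bp, an alternative chosen after seeing the data, the shift was -0.23 and passed (camera in limma, adjusted p = 0.000409, and adjusted p = 0.0234 with an estimated correlation). It also passed with 3 kb when sgPrdm12-2 was left out, at -0.18. Gene bodies, other genes and intergenic regions did not pass. Of 21 chromosomes 0 passed the camera test, with the median of chromosome X at -0.13 (limma, adjusted p = 0.912). Without sgPrdm12-2, chromosome Y passed with a mean shift of -0.47 (limma, adjusted p = 0.0066), on 19 regions in the fit of all libraries.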

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

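The authors' constants, leaving out the 10 most covered regions, gene spans without flanks and gene ends of 1000 bp were tried only after the data were seen. The 24 named regions kept their direction in each alternative that gave them a value. This was largely fixed by the naming rule, which required both sgPrdm12 libraries on the same side of both sgNTC libraries. Direction was also taken relative to the median region, so it says little about how firm the calls are. With total counts, no filter, the replicate block and the authors' constants all 24 also passed the threshold. Of the 12 higher and 12 lower ones, 2 and 9 passed with DESeq2 size factors, 6 and 11 without the 10 most covered regions, 0 and 7 with DESeq2's Wald test, which gave the higher ones no adjusted p, and 0 and 6 with limma-voom, where Flg2 and Stat5b were among those that did not pass. The replicate block gave 45 regions higher and 170 lower, 71 and 120 genes, and a zinc finger shift of 0.28, and it changed no call of a named region, named gene, list or class. Region counts with DESeq2 size factors were 3 higher and 57 lower, and 29 genes were higher. With total counts they were 936 and 79, with 1177 and 70 genes, 3 lists past the threshold and Prdm12 at 0.60 relative to the median gene and past the threshold. With the authors' constants they were 7765 and 52, with 3445 and 32 genes, 3 lists and Prdm12 at 0.61 and past the threshold. With the authors' constants and replicate block they were 6769 and 53, with 3359 and 30 genes, 3 lists and Prdm12 at 0.61. These settings shift the zero of the scale by construction. Without the 10 most covered regions 19 regions were higher and 79 lower. DESeq2's Wald test called 6 regions higher, and 6 genes higher and 63 lower, with no adjusted p for 34795 regions. limma-voom called 1 region and 31 genes higher. At an adjusted p threshold of 0.1, 58 regions were higher and 169 lower. With gene spans only, 56 genes were higher and 82 lower, and values turned for the H3K9 machinery (-0.0077), cytochrome P450 genes (-0.062) and Rasgrf1 (0.16). With no filter the germline list turned to -0.055, and with the region as the unit the protocadherin list turned to -0.016. With an estimated correlation 0 lists passed, and the zinc finger shift of 0.27 no longer did. Gene ends of 1000 bp stood at -0.23 and passed, which made 1 class past the threshold. The cause was not tested where none is named.

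Leaving out each library in turn, with a lone library assumed to vary like the other group, gave 6 to 56 regions higher and 29 to 219 lower, 15 to 63 genes higher and 70 to 184 lower, 0 to 1 lists, 0 to 1 region classes and 0 to 1 chromosomes past the threshold. The zinc finger shift ranged from 0.15 to 0.31 and gene ends from -0.18 to -0.12. Unpassed lists changed sign, with ranges of -0.23 to 0.71 for the H3K9 machinery, -0.020 to 0.52 for imprinted genes, -0.19 to 0.0030 for germline genes, -0.029 to 0.19 for cytochrome P450 genes, -0.20 to 0.35 for protocadherins, -0.48 to 0.092 for effector genes, -0.37 to 0.024 for nociceptor genes, -0.23 to 0.032 for olfactory receptors and -0.24 to 0.10 for the PRDM family. Tac1 ranged from -0.038 to 1.74.

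A threshold on a peak score, a distance to the transcription start and the pseudocount were not run, since the table used has counts and no such columns. With 7 and 9 counts in the median region of sgNTC, changes of 1 on the log2 scale were mostly below what the region test recovered in simulation (3.64%).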

Other observations

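The tests of the few most covered regions, of coverage bands and of narrow against wide regions were chosen after the results were seen, as were the gene groups of the next paragraph, and the zinc finger match on mean CPM replaced a planned match on mean count after that result was seen.

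H3K9me3 rose at part of the epidermal differentiation complex on chromosome 3, a cluster of skin barrier genes. Of 18 measured genes, 3 rose and 0 fell, namely Flg2, Flg and S100a7l2, at 1.61, 1.23 and 1.18, and 7 of the 41 regions of the 18 genes were called higher. The group's median was -0.14, as Lelp1 and Sprr2a2 stood at -0.68 and -0.81. No set test is given for this group, because it was drawn up after Flg2 and Flg were seen to rise. Near the assembled starts of chromosomes, in the first 0.2 Mb of sequence, the median of 141 tested regions was -0.51, and 27 were lower and 0 higher. Of the 27, 16 lay on chromosome 9. Heavily covered regions at the start of chromosome 10 went the other way, at 0.65 to 0.89, though none passed. In the gene fit 9230019H11Rik, which lies there, was called higher at 0.73. The heavily covered gene 2700054A10Rik on chromosome 17 rose by 0.54, by 0.22 in batch 1 and 0.80 in batch 2. It had 11066 and 12593 counts in sgNTC against 52974 and 42961 in sgPrdm12. Its most covered regions, at 0.57 and 0.48, did not pass singly, and the gene fit could give smaller p-values for the same counts.

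The median region was higher in sgPrdm12 with total counts (0.56) and the authors' constants (1.00). With totals taken without the 10 most covered regions the median was 0.10. A few regions taking a large share of the counts, larger in sgNTC, may therefore account for the shift with total counts. With the authors' constants, regions between the 95th and 99th percentile of coverage still had a median of 1.08 (bootstrap SE 0.02). The top 1% had one of 0.69 (bootstrap SE 0.07). The shift was thus not confined to thinly covered regions. However, the constants move all regions alike, and on the TMM scale these bands stood at 0.07 and -0.32. The values therefore cannot decide whether regions were called at the detection limit of the sgPrdm12 libraries. A contrast of the band between the 95th and 99th percentile with the least covered regions decided nothing either. It was -0.08 when regions were ranked by mean CPM and 0.42 when ranked by mean count. More reads inside regions because of a better signal over background, and a gain of H3K9me3 after targeting of Prdm12, stay open and untested, as the IgG library was not analysed here.

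Regions within 250 bp of the ends of protein-coding genes differed from the rest by -0.46 (bootstrap SE over regions 0.06). The difference shrank to -0.10 within 3000 bp. All 4 pairings of an sgPrdm12 with an sgNTC library gave a negative difference, the nearest to 0 being -0.43 (bootstrap SE 0.06). A single library is thus argued against, although pairings share libraries and the SE holds no spread between libraries. More untargeted cutting of open chromatin in the sgNTC libraries is a candidate explanation. Away from gene ends, among the 5% most covered regions, those narrower than 400 bp were lower than wider ones of like CPM in both batches, by -0.58 in the batch with the smaller difference. The test is indirect, because a loss of H3K9me3 at narrow sites after targeting of Prdm12 would give the same value and stays open. Region widths also come from the region calling, which is not described. If it gave more weight to the deeper sgPrdm12 libraries, regions high there could be called wider, with the same result. The test therefore cannot decide between these.

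Zinc finger genes stood higher by 0.25 in batch 1 and 0.26 in batch 2, as medians relative to all genes. Their median lay at percentile 100 of 10000 random lists matched on number of regions and mean CPM, at percentile 100 when matched on mean count, and at percentile 100 when region width was matched as well, which argues against abundance, region number and width as the whole cause. Neighbours counted as independent are argued against too, since 71.4% of 70 clusters lay above the median of all genes (exact binomial p = 0.00044). These tests do not cover a factor shared by a whole library. The list did not pass without sgNTC-1 or with an estimated correlation, although the estimate itself was -0.00036. A better signal over background in the sgPrdm12 libraries and an effect of Prdm12 both stay open, the latter as an untested hypothesis.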
